A study of Homo sapiens with 30 samples.

How the data were processed

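The samples were 30 cultures of stimulated PBMCs from 15 donors, one culture without and one with IFN-beta for each donor. Per the labels' protocols, total RNA was extracted with a column kit and biotinylated cRNA was prepared from 7 µg of it for Affymetrix human U133 arrays. Each sample's group and donor number were taken from its title in the labels. The numbers pair the arrays because the labels assign each number to 1 donor, whose cells were used in both conditions. The deviations from the group means correlated between the arrays of a pair with r between 0.378 and 0.886 (median 0.801, across genes, which are not independent replicates), against a median of −0.0783 between arrays of different donors. For 13 of the 15 arrays with IFN-beta the array of the same donor was the best match. No 2 columns were identical, and array correlations lay between 0.9375 and 0.9976.

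The deposited values are on a log scale taken as log2, with 1 value per probe set and array (54675 probe sets). The log base, the background correction and the normalization between arrays are not given in the sources used here. Log2 was taken from the range of the values, from −0.0892 to 16.3, whose upper end lies near the log2 of the largest reading of a 16-bit scanner. The submitters' processing notes name MAS5, without a version, and the series' design text names the matching software suite for washing, scanning and basic analysis. The narrow low mode at 2.4 is tighter than plain MAS5 signals usually are, so a further step by the authors stays open. The deposited values do not share a single distribution across arrays, since their 99th percentiles ran from 12.4 to 13.2. This does not show whether the probes were normalized before they were combined into probe sets. In ascending order the array medians without IFN-beta were 2.94, 2.94, 2.96, 2.97, 2.97, 2.98, 3.02, 3.06, 3.09, 3.10, 3.12, 3.12, 3.12, 3.20 and 3.21. Those with IFN-beta were 2.92, 2.93, 2.95, 2.96, 2.99, 3.00, 3.02, 3.06, 3.06, 3.08, 3.09, 3.10, 3.10, 3.13 and 3.18. Scale factors between arrays stay unknown. The direction of a change follows from the labels, and values were neither centred per gene nor ratios. There were no missing values, and 30 values, 1 on each array, lay below 0. If the log base were another one, fold changes would change and tests would not.

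The design written before the data were examined allowed for linear values with an offset before the log. The deposited values were already logged, so they were used as they are, and a floor at the 5th percentile and an offset equal to the median of all values (8.27 on the linear scale) were tried as alternatives. The 62 control probe sets were left out. Genes were named through the platform's annotation: 41091 probe sets had 1 gene symbol, 1801 several and 11721 none. Entrez identifiers matched a RefSeq gene table of assembly GRCh38.p14, used only for names, for 41037 of the 1-symbol probe sets with no symbol changed, and were not matched for 54, which kept their symbol. Genes of the Y chromosome and XIST (59 probe sets) were left out. No coordinates are given, because the sources used here name no genome build. Probe sets in the lowest 40% by mean over all arrays (mean log2 of 2.746 or less) were left out, and each gene was represented by the brightest of its remaining 1-symbol probe sets. This gave 13750 genes from 32768 probe sets, 6416 of them with several probe sets.

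Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with the donor as a fixed block and IFN-beta as the tested term, and p-values were adjusted with the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 were called, and "rose" and "fell" refer to these. Lists of genes, 27 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the 27 lists, and beside it with an estimated correlation and with fry. Of the 27 lists 13 passed with the preset correlation and 2 with an estimated one, and 15 passed fry, which tests whether a list's own genes move one way and does not compare them with other genes. Members whose names were not found on the table or that lay below the level filter were not tested, and the counts given are of tested members. Paired differences of single values (list means, array measures) were tested with exact sign-flip tests over the 15 pairs, 2-sided. An exact sign test of the array measures was added after seeing the data.

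The genes named in the report follow a rule fixed before the data were examined. Among genes past the threshold that moved one way in at least 12 of 15 pairs, it takes the 15 largest increases and the 15 largest decreases. To these it adds 20 genes fixed by name, whatever their test, and up to 4 members of each list with the smallest adjusted p. It gave 133 tested genes, 54 with several probe sets, of which 2 had a probe set of opposite sign (CFB and CD79B) and 0 had one past the threshold. Calls of second or several probe sets of a gene were adjusted over all 32768 probe sets, which is stricter than over 13750 genes. IL17F, IL6, IL12RB2 and BTLA have 1 probe set each, past the threshold among genes but not among probe sets. The adjusted p of CFB's second probe set comes from the setting without probe sets of possible cross-hybridization. Not every gene fixed by name is reported here. IFITM1, JAK2, SOCS1, PIAS1, STING1, ERAP1, CXCL2, TNFSF4, CXCR4, CD3D, GNLY, EIF2AK2, RIGI, PSMB9 and CD83 fall outside the rule and were named after their values were seen, to complete a small count, to give a range or to name a call that changed without 4 pairs.

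The fit was tested on simulated data with the donors, the genes and the spread of the real comparison but independent noise between genes. Among 13750 simulated genes with 50 changed at each size, 42% of changes of 0.25 log2 were recovered, 90% of those of 0.5, 92% of those of 1 and 100% of those of 2, and 4 of 166 calls were false. Alternatives fixed beforehand were no replicate block, the donor as a random block, quantile normalization, median centring, the floor, the offset, no level filter, the lowest 60% left out, the mean of all probe sets of a gene, leaving out probe sets of possible cross-hybridization (identifiers ending in _x_at or _s_at), a trended and robust prior, an exact signed-rank test per gene, a covariate for RNA quality, and leaving out each pair in turn. Leaving out the 4 pairs with an ACTB 3′ to 5′ ratio above 3 on either array was added after seeing the data. Figures were drawn with matplotlib 3.10.9.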

Results

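Gene expression was measured in peripheral blood mononuclear cells (PBMCs), the lymphocytes and monocytes of the blood, from 15 donors with CIS. The labels do not spell out this abbreviation; beside interferon-beta treatment it commonly stands for clinically isolated syndrome, a first episode of demyelination. Equal numbers of cells were stimulated for 24 h in serum-free medium with plate-bound antibodies against CD3 (1 µg/ml) and CD28 (5 µg/ml), which activate T cells. The cells of each donor were cultured without and with interferon-beta-1a (IFN-beta) at 1000 U/ml, so the 30 arrays form 15 donor pairs. The comparison asks which transcripts IFN-beta changes in cells that are being activated through the T cell receptor. Values are log2 signals of Affymetrix U133 arrays, and the number of arrays limits their precision. Array medians lay between 2.92 and 3.21, and 63.5% of all values were below 4, close to the low mode of 2.4 at which dim probe sets accumulate. The 3′ to 5′ signal ratio of ACTB, a sign of RNA integrity, was above 3 on 7 arrays from 4 pairs, of which 3 were without and 4 with IFN-beta. The log2 ratio itself differed between the conditions by −0.066 ± 0.993 (SD, n = 15 pairs, exact sign-flip test, 2-sided, p = 0.975, adjusted over 7 array measures 0.975). This measure of array quality turned to 0.0554 without those 4 pairs (exact p = 0.043) and to 0.172 when 1 pair was left out (exact p = 0.0497), past 0.05 in both. Of the other array measures, the 99th percentile was higher with IFN-beta in 14 of 15 pairs (sign test, p = 0.000977, adjusted over the 7 measures 0.00684), by 0.0305 ± 0.146 on the mean (exact sign-flip test, p = 0.479). The share of signal in the 100 brightest probe sets was 16.2% without and 15.7% with IFN-beta, lower in 11 of 15 pairs (exact sign-flip test, p = 0.0212, adjusted over the 7 measures 0.148).

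IFN-beta raised all 37 tested antiviral genes of a fixed list, while 5 of 6 neutrophil-attracting chemokines, 4 of 7 cytokines that favour Th17 cells and 3 of 13 matrix metalloproteinases and inhibitors fell. With an estimated correlation these 4 lists did not pass against other genes (adjusted p = 0.0615, 0.181, 0.109 and 0.195). Without the 4 pairs with an ACTB ratio above 3, 35 of the 37 antiviral genes rose, and 1 of 6, 3 of 7 and 2 of 13 genes of the other lists fell. Monocyte markers had a median change of −0.684 over all pairs and −0.208 without those 4, with none past the threshold. Of 13750 genes tested, 1544 passed an adjusted p of 0.05, with 818 higher and 726 lower with IFN-beta. Which direction held more calls depended on the setting: 744 were higher and 944 lower after quantile normalization, 868 and 593 after median centring, and 808 and 831 with the signed-rank test. Of these, 139 changed at least 2-fold, with 89 higher and 50 lower. Among the called genes 161 were higher and 94 lower in all 15 pairs, while chance alone would give 0.84 genes that move one way in every pair. With the paired analysis set aside, so that the replicate block was dropped, 142 genes passed (120 higher, 22 lower), 63 of them by at least 2-fold, and 64 of the 89 calls among the genes named by the fixed rule were lost. That fit ignores the pairing and leaves the spread between donors in the error, here and wherever it is named below. Without the 4 pairs above the ACTB ratio limit, an alternative chosen after seeing the data, 1055 genes passed (637 higher, 418 lower), 82 of them by at least 2-fold.

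The largest increase was that of IFI27, a mitochondrial interferon-inducible protein, from 5.80 ± 2.55 to 10.77 ± 0.90 (mean ± SD, n = 15, log2 change 4.97, SE 0.64, adjusted p = 0.000424). CXCL11, a ligand of the chemokine receptor CXCR3, rose 15.9-fold (7.60 ± 2.26 to 11.59 ± 1.68, adjusted p = 0.000334). IFIT1, which binds viral RNA, rose 9.55-fold, and USP18, which removes ISG15 from proteins and dampens interferon receptor signalling, rose 8.83-fold. The other genes among the 15 largest increases were BCL2L14, CFB, NEXN, ENPP2, ZBP1, MX2, SERPING1, CCNA1, SIGLEC1, ELOVL7 and IFIT2, with increases between 4.42-fold for IFIT2 and 7.84-fold for BCL2L14. A second probe set of BCL2L14 changed by 0.00986 on the log2 scale and did not pass. The complement factor CFB rose 7.83-fold on its brightest probe set, while a second probe set gave a log2 change of −0.117 that did not pass the threshold (adjusted p = 0.372). CCNA1 lay at 2.55 ± 0.24 without IFN-beta, near the low mode of the arrays, so that its 4.72-fold increase is set by the background on one side. The log2 changes of CCNA1, SIGLEC1 and ELOVL7 were 1.78, 1.76 and 1.87 without the 4 pairs above the ACTB ratio limit, in place of 2.24, 2.23 and 2.15, and no longer passed (adjusted p = 0.0631, 0.0508 and 0.0717). SERPING1 and ELOVL7 did not pass without the replicate block (adjusted p = 0.125 and 0.101).

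With each gene represented by its brightest probe set, the largest decrease was that of MRC1, the macrophage mannose receptor, which was 10.5-fold lower with IFN-beta (9.13 ± 2.27 to 5.75 ± 2.98, SD, n = 15, log2 change −3.39, SE 0.53, adjusted p = 0.0009) and lower in all 15 pairs. MMP9, a gelatinase, was 9.91-fold lower, also in all 15 pairs. Its log2 change was −2.22 without the 4 pairs above the ACTB ratio limit, in place of −3.31. TNFSF15, a TNF family cytokine, was 8.51-fold lower, and CLEC5A, a receptor of myeloid cells, was 7.82-fold lower. CXCL5, MMP1, MUCL1, IL1A, CHI3L1, CCL22, PI3, CD93, F3, FBP1 and MCEMP1 completed the 15 largest decreases, between 6.57-fold for CXCL5 and 3.82-fold for MCEMP1. The 3 probe sets of CXCL5 ran from −4.09, beyond the change of MRC1, to −1.26, and second probe sets of IL1A and CD93 changed by −0.0253 and −1.07 and did not pass. F3 encodes tissue factor, which starts the clotting cascade, and fell 4.30-fold. Without the 4 pairs above the ACTB ratio limit MUCL1, CHI3L1, PI3 and MCEMP1 did not pass (adjusted p = 0.139, 0.112, 0.0861 and 0.0598), with log2 changes of −1.47, −1.45, −1.84 and −1.18 in place of −2.52, −2.38, −2.14 and −1.93. Of these 15 decreases, MRC1, MMP9, CLEC5A, CXCL5, MMP1, MUCL1, CHI3L1, CCL22, PI3, CD93, FBP1 and MCEMP1 did not pass without the replicate block. Monocyte markers, described below, had a median change of −0.684 over all pairs and −0.208 without the 4 pairs, with none past the threshold. For decreases of myeloid genes, a smaller share of monocytes cannot be told apart from lower expression per cell.

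**Figure D1:**
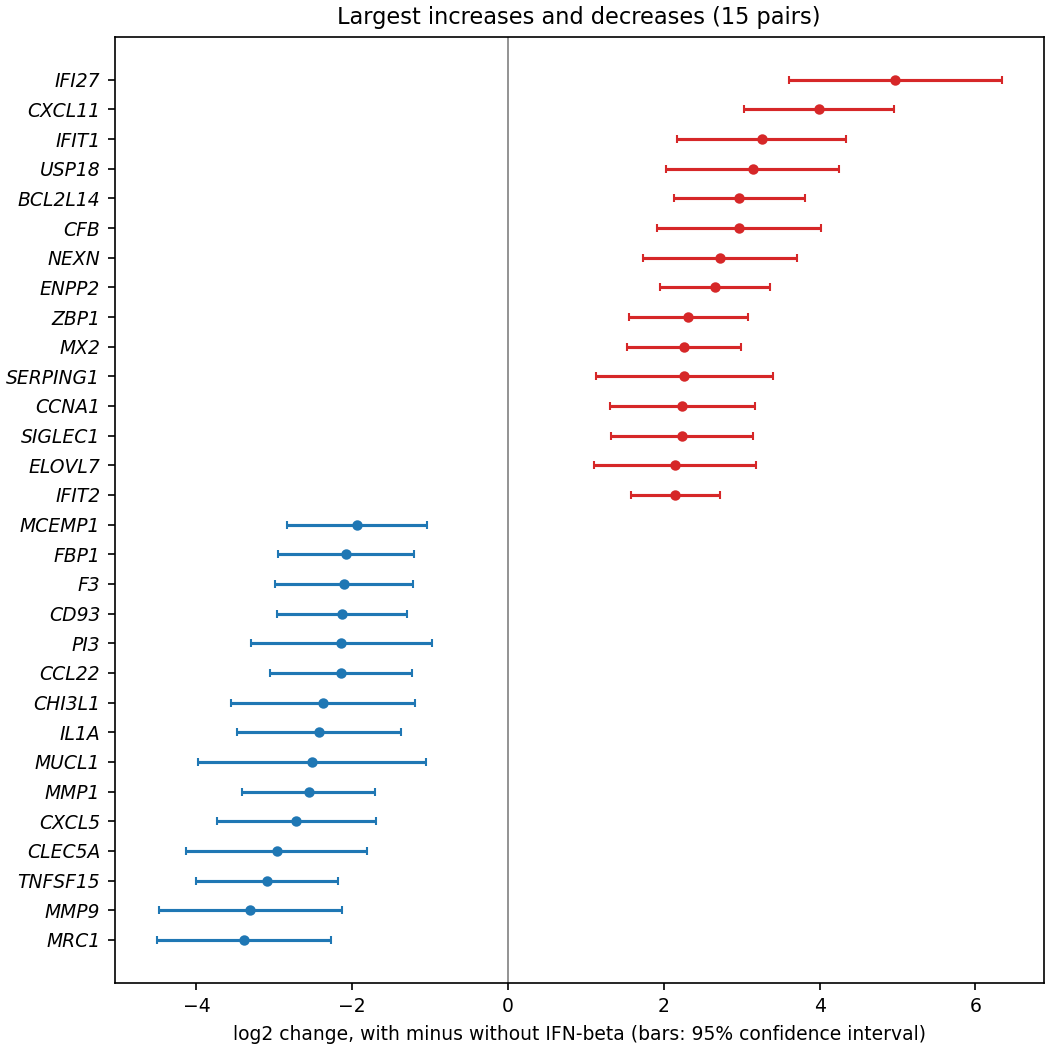
Log2 change (with minus without IFN-beta, horizontal axis) of the 15 genes with the largest increases (red) and the 15 with the largest decreases (blue) among genes past the threshold that moved one way in at least 12 of 15 pairs. Points are means over the 15 donor pairs and bars are 95% confidence intervals, from IFI27 at 4.97 to MRC1 at −3.39.

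All 37 genes of the fixed list of antiviral interferon-stimulated genes rose, by 0.54 to 4.97 on the log2 scale with a median of 1.49. The list holds the effector families IFIT, OAS, MX and IFITM, which act against viral RNA, replication and entry. IFIT2 was already high at 11.54 ± 1.28 without IFN-beta and rose 4.42-fold (SD, n = 15), MX2 rose 4.80-fold, OASL 4.30-fold and IFI35 2.33-fold. IFITM1 had the smallest increase, 1.45-fold. EIF2AK2 and SIGLEC1 did not pass without the 4 pairs above the ACTB ratio limit (adjusted p = 0.0565 and 0.0508), with log2 changes of 0.725 and 1.76 in place of 0.947 and 2.23. Against the other genes on the arrays the list was higher (camera with a preset correlation of 0.01, adjusted p = 7.34e-48). With a correlation estimated from these arrays the camera test did not pass (adjusted p = 0.0615).

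The size of the antiviral response differed widely between donor pairs. Each donor had a single culture and array per condition, so differences between donors, cultures and arrays cannot be told apart. The mean over the 37 genes was 10.7 ± 0.979 without IFN-beta and 12.3 ± 0.405 with it (SD, n = 15). It was higher with IFN-beta in 15 of 15 pairs, by 1.64 ± 0.898 (3.11-fold at the mean, exact sign-flip test, 2-sided, p = 6.1e-05, the smallest p that 15 pairs allow). The change per pair ran from 0.147 to 2.81. Levels ran from 8.74 to 12.3 without IFN-beta but only from 11.5 to 12.9 with it, and 36 of the 37 genes had the larger SD without IFN-beta. Swapping the conditions within pairs after centring each condition gave a difference in spread as large with an exact p of 0.00513.

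**Figure D2:**
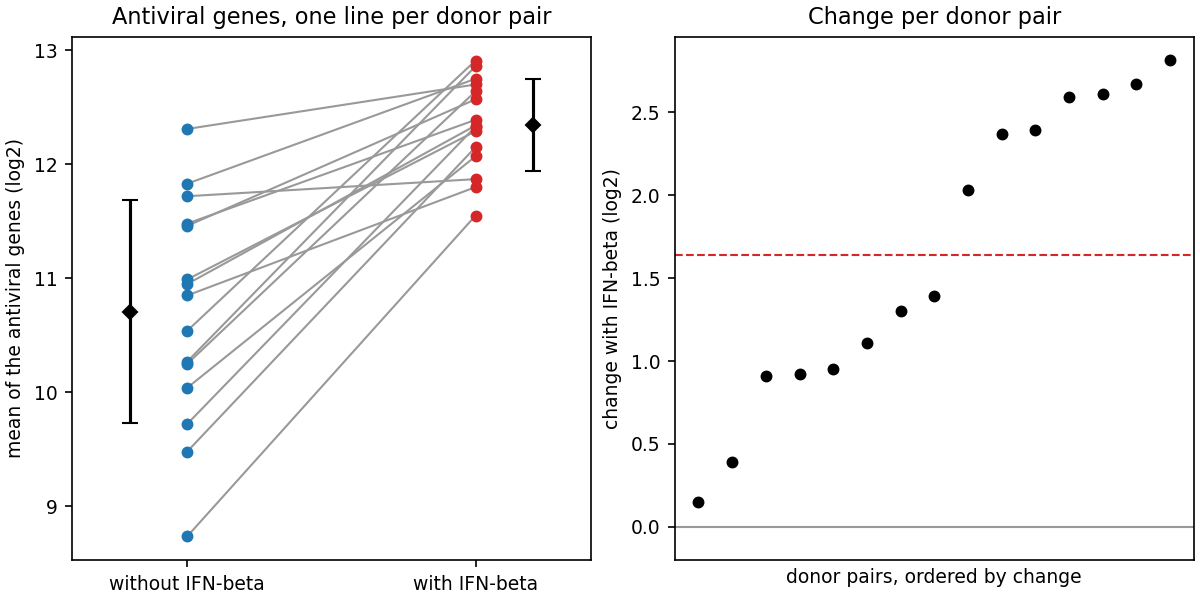
Left, mean log2 signal of the 37 antiviral genes in each culture, without (blue) and with IFN-beta (red), with a line per donor pair and the group mean ± SD in black (10.7 ± 0.979 and 12.3 ± 0.405). Right, the change of each of the 15 pairs in log2, ordered by size, from 0.147 to 2.81, with the mean of 1.64 as a dashed line.

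Transcripts of interferon signalling rose in part. Of 24 tested members of the list of interferon receptors, JAK kinases, STAT and IRF factors and their regulators, 7 rose, none fell and 17 did not pass (8 rose when adjusted over the list alone). IRF7, a factor that amplifies type I interferon responses, rose 2.46-fold, IRF8 1.49-fold, IRF2 1.43-fold and IRF9 1.30-fold. The other members that rose were JAK2 and 2 inhibitors of the pathway, SOCS1 and PIAS1, by 1.46-fold, 1.24-fold and 1.18-fold, of which PIAS1 did not pass without the 4 pairs above the ACTB ratio limit (log2 change 0.164 in place of 0.238, adjusted p = 0.181). The receptor chains IFNAR1 (log2 change −0.27, SE 0.13, adjusted p = 0.228) and IFNAR2 (−0.11, SE 0.11, adjusted p = 0.567) and the feedback inhibitor SOCS3 (0.08, SE 0.14, adjusted p = 0.748) did not pass. The list as a whole was higher than other genes with the preset correlation (adjusted p = 8.92e-06) and did not pass with an estimated one (adjusted p = 0.109).

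The list of nucleic acid sensors and Toll-like receptors was higher as a whole, through part of its members. Of 20 tested sensors, adaptors and Toll-like receptors, 8 rose, 1 fell and 11 did not pass, with a list median of 0.33. TLR7, an endosomal receptor for single-stranded RNA, rose 3.20-fold (4.56 ± 1.19 to 6.24 ± 1.06, SD, n = 15, adjusted p = 0.000894) and was higher in 15 of 15 pairs. ZBP1, a sensor of Z-form nucleic acids, rose 4.97-fold on its brightest probe set, with a log2 change of 1.03 on a second one that did not pass. IFIH1, the RNA helicase MDA5, rose 2.25-fold and IFI16 1.48-fold. RIGI, another RNA helicase that rose, did not pass without the 4 pairs above the ACTB ratio limit (log2 change 0.648 in place of 0.916, adjusted p = 0.0857). STING1, the adaptor of the cytosolic DNA pathway, fell (log2 change −0.529, adjusted p = 0.0109). This list passed with the preset correlation (adjusted p = 8.92e-06) and with an estimated one (adjusted p = 0.0247).

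Of 17 tested class I genes 6 rose and 1 fell, and 10 did not pass (10 rose and 1 fell when adjusted over the list alone). The changes were small: the peptide transporter subunits TAP1 and TAP2 rose by 0.349 and 0.298 on the log2 scale, HLA-E by 0.266 and HLA-F by 0.192. The list median was 0.0978, with an adjusted p of 1.24e-05 with the preset correlation and an adjusted p of 0.109 with an estimated correlation. ERAP1, an aminopeptidase that trims peptides for class I, was the gene that fell (log2 change −0.193, adjusted p = 0.0453). In the pairs below the ACTB ratio limit 4 class I genes rose and none fell, as ERAP1, TAP2 and PSMB9 did not pass there (adjusted p = 0.35, 0.0546 and 0.0963), with log2 changes of −0.115, 0.219 and 0.178 in place of −0.193, 0.298 and 0.252. Of 14 class II genes 1, HLA-DOA, fell by 0.353 on the log2 scale (−0.0391 on a second probe set, not past the threshold), none rose and 13 did not pass. Among these 13, LGMN, a lysosomal protease, had a log2 change of 0.807 (adjusted p = 0.115), higher in 14 of 15 pairs, and rose in the pairs below the ACTB ratio limit (0.417, adjusted p = 0.0238), where HLA-DOA also fell. The class II list had a median of −0.215 and did not pass (adjusted p = 0.0997), although it did after each array was centred on its median (adjusted p = 0.0456). Probe sets of the HLA genes can pick up more than 1 member of the family, so single HLA values are uncertain. Whether the class I and class II lists differed was not tested.

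Part of the interferon-inducible chemokines rose and most neutrophil-attracting chemokines fell; the difference between the groups was not tested. Of 9 interferon-inducible and monocyte-attracting chemokines 4 rose and 5 did not pass. CXCL11 was described above, CCL19, which guides cells bearing CCR7, rose 3.40-fold, CXCL10 2.43-fold and CCL4 1.27-fold. As a list they passed with the preset correlation (adjusted p = 0.000122) but not with an estimated one (adjusted p = 0.109). Of 6 neutrophil-attracting chemokines, ligands of CXCR1 and CXCR2, 5 fell and 1 did not pass, with a median of −1.33. CXCL5 was 6.57-fold lower (13.07 ± 1.41 to 10.35 ± 2.46, SD, n = 15, adjusted p = 0.00199), and CXCL3 and CXCL1 fell by 1.91 and 1.47 on the log2 scale. CXCL2 fell by 1.18. CXCL8 fell by 0.454 on its brightest probe set, at 14.8 without IFN-beta and changed by −1.18 on its other one. Together the 6 genes passed with the preset correlation (adjusted p = 8.31e-05) but not with an estimated one (adjusted p = 0.181). Without the 4 pairs above the ACTB ratio limit 1 of the 6, CXCL5, passed, and CXCL8, CXCL1, CXCL2 and CXCL3 had adjusted p of 0.0597, 0.0822, 0.0854 and 0.0735, with log2 changes of −0.375, −1.06, −0.85 and −1.24. The median of the list was then −0.953. Monocyte markers, described below, had a median change of −0.684 over all pairs and −0.208 without the 4 pairs, with 0 of 10 past the threshold in either.

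Of 7 tested cytokines that favour Th17 cells, the T helper cells that make IL-17, 4 fell and 3 did not pass, with a median of −0.874. When the 4 pairs above the ACTB ratio limit were left out, 3 fell and the median was −0.513. The median change of the monocyte markers was −0.684 (−0.208 without those pairs). IL1B was 2.37-fold lower (13.39 ± 0.96 to 12.14 ± 1.32, SD, n = 15, adjusted p = 0.00808) and lower in 14 of 15 pairs. IL6 was 2.41-fold and SPP1, osteopontin, 1.83-fold lower, and IL1A was 5.38-fold lower on 1 of its 2 probe sets, with −0.0253 on the other. IL23A (log2 change −0.18, SE 0.15, adjusted p = 0.484) and IL12B (−0.14, SE 0.10, adjusted p = 0.418) did not pass. The list passed with the preset correlation (adjusted p = 0.00169), but not with an estimated one (adjusted p = 0.109) nor with probe sets of possible cross-hybridization left out (adjusted p = 0.0552). IL6 did not pass without the 4 pairs above the ACTB ratio limit (log2 change −0.954 in place of −1.27, adjusted p = 0.106), and without the replicate block IL1B, IL6 and SPP1 did not pass (adjusted p = 0.194, 0.701 and 0.723).

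Of 12 tested genes of the Th17 programme 3 fell and 9 did not pass (5 fell when adjusted over the list alone), with a median of −0.385. IL17F was 2.69-fold lower (8.74 ± 1.85 to 7.31 ± 2.33, SD, n = 15, adjusted p = 0.0414) and lower in 12 of 15 pairs. IL17A had a log2 change of −1.04 (SE 0.40), lower in 11 of 15 pairs, and did not pass (adjusted p = 0.115). The other members that fell are not made by Th17 cells alone: KLRB1, the receptor CD161 of NK and T cell subsets, fell by 1.43, and IL1R1, the receptor of IL-1, fell by 1.13 and in all 15 pairs, with −0.0774 on a second probe set that did not pass. CCR6, a homing receptor of Th17 cells, had a log2 change of −0.19 (SE 0.08, adjusted p = 0.175). The list passed with the preset correlation (adjusted p = 0.00169) but not with an estimated one (adjusted p = 0.181). IL17F did not pass without the 4 pairs above the ACTB ratio limit (log2 change −1.17 in place of −1.43, adjusted p = 0.188), nor without the replicate block (adjusted p = 0.74).

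Among 5 tested cytokines that oppose Th17 cells or regulate inflammation, IL10 rose 2.80-fold (6.07 ± 1.54 to 7.56 ± 2.31, SD, n = 15, adjusted p = 0.00644) and was higher in 12 of 15 pairs, and 4 did not pass. Without the replicate block IL10 did not pass (adjusted p = 0.611). EBI3, a chain of IL-27 and IL-35, had a log2 change of −0.04 (SE 0.15, adjusted p = 0.892). The list had a median of 0.304 and did not pass (adjusted p = 0.0654). IL27 and IL12A were below the level filter, with means of 1.46 and 2.38 without IFN-beta, at or below the low mode of the arrays, and were not tested. Of 16 genes of the inflammasome and the IL-1 family, some of them shared with the Th17 lists, 1 rose, GSDMD by 1.25-fold, and 3 fell, IL1A, IL1B and IL1R1 (3 and 4 when adjusted over the list alone). GSDMD did not pass without the 4 pairs above the ACTB ratio limit (log2 change 0.232 in place of 0.324, adjusted p = 0.222), which left no rise in this list. The median of this list was 0.052 and its mean −0.207, so that they differ in sign, and it did not pass (adjusted p = 0.992).

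For the other T helper programmes, 2 of 9 tested Th2 genes fell and 7 did not pass (5 fell when adjusted over the list alone). The genes that fell were CCL22, a chemokine made by macrophages and dendritic cells, which was 4.43-fold lower, and its receptor CCR4, which fell by 0.421 from 3.48, close to the background. The Th2 list had a median of −0.308 (adjusted p = 0.00866 with the preset correlation, adjusted p = 0.203 with an estimated correlation). Of 12 Th1 genes the receptor chain IL12RB2 rose 1.83-fold, IL18R1 fell by 0.365, and 10 did not pass (4 rose and 2 fell when adjusted over the list alone). Neither IL12RB2 nor IL18R1 passed without the 4 pairs above the ACTB ratio limit (log2 changes 0.745 and −0.396 in place of 0.873 and −0.365, adjusted p = 0.169 and 0.0823). IFNG, the main Th1 cytokine, had a log2 change of 0.68 (SE 0.48, adjusted p = 0.418) and was higher in 6 of 15 pairs, and the Th1 list did not pass (adjusted p = 0.193). Of 9 regulatory T cell genes IL10RA rose 1.42-fold, TNFRSF4 fell by 0.507, and 7 did not pass, among them FOXP3, the defining factor of these cells (log2 change −0.41, SE 0.17, adjusted p = 0.139). This list did not pass either (adjusted p = 0.392).

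Inhibitory receptors and their ligands rose as a group, with 4 of 12 rising, 8 not past the threshold and a median of 0.53. LGALS9, the ligand galectin-9, rose 1.95-fold, LAG3 1.91-fold, CD274, the ligand PD-L1, 1.39-fold and BTLA 1.31-fold. The list passed with the preset correlation (adjusted p = 3.75e-05) and with an estimated one (adjusted p = 0.0247). CD274 (log2 change 0.482 in place of 0.477, adjusted p = 0.0878) and BTLA (0.332 in place of 0.386, adjusted p = 0.192) did not pass without the 4 pairs above the ACTB ratio limit, and without the replicate block LAG3, CD274 and BTLA did not (adjusted p = 0.278, 0.525 and 0.999). Of 16 genes of T cell activation and costimulation 4 rose and 1 fell (4 and 4 when adjusted over the list alone): CD80 rose 2.57-fold, TNFSF4, the ligand OX40L, 1.94-fold, ICOS 1.28-fold and CD69 1.27-fold, while TNFRSF4, the receptor OX40, fell by 0.507. CD80 and TNFSF4 did not pass without the 4 pairs (log2 changes 0.902 and 0.776 in place of 1.36 and 0.959, adjusted p = 0.052 and 0.218), while CD83 fell there (log2 change −0.327 in place of −0.272, adjusted p = 0.0444). That list did not pass (adjusted p = 0.543).

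Of 18 apoptosis genes 7 rose and 11 did not pass (8 rose when adjusted over the list alone), with a median of 0.141. The death ligands TNFSF10, which encodes TRAIL, and FASLG rose 3.26-fold and 2.36-fold and the receptor FAS 1.48-fold, each in 15 of 15 pairs. CFLAR, which restrains signalling from death receptors, also rose, by 1.26-fold. The list passed with the preset correlation (adjusted p = 4.32e-06) but not with an estimated one (adjusted p = 0.0615). Of 23 cell cycle genes 1 fell, TYMS, the thymidylate synthase, by 0.869 (−0.422 on a second probe set, not past the threshold), and 22 did not pass. The cell cycle list had a median of −0.24 and an adjusted p of 0.0207 with the preset correlation. It did not pass with an estimated correlation (adjusted p = 0.627), with no level filter (adjusted p = 0.0623), without the 4 pairs above the ACTB ratio limit (adjusted p = 0.0648), or when 1 of the 15 pairs was left out (adjusted p = 0.0577).

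Of 13 tested matrix metalloproteinases and their inhibitors 3 fell and 10 did not pass (4 fell when adjusted over the list alone), with a median of −0.695. Without the 4 pairs above the ACTB ratio limit the median was −0.262 and 2 fell. The monocyte markers had a median of −0.684 over all pairs and −0.208 without the 4. MMP9 was 9.91-fold lower (10.44 ± 2.49 to 7.13 ± 3.06, SD, n = 15, adjusted p = 0.00145), and MMP1, an interstitial collagenase, was 5.90-fold lower. Both still passed without the 4 pairs, with log2 changes of −2.22 for MMP9 and −2.44 for MMP1 in place of −3.31 and −2.56. MMP10 fell from 4.63 ± 2.17 to 2.87 ± 0.63, near the low mode of the arrays, so that its size is limited by the background, and it did not pass without the 4 pairs (log2 change −1.77 in place of −1.76, adjusted p = 0.0727). With the preset correlation this list passed (adjusted p = 0.00225), but not with an estimated one (adjusted p = 0.195). Of 15 adhesion and homing genes 1 rose and 4 fell (1 and 6 when adjusted over the list alone). CCR7, the receptor that directs lymphocytes to lymph nodes, rose 1.29-fold in 15 of 15 pairs. The integrin chains ITGAM, ITGB2 and ITGB1 fell by 1.33, 0.792 and 0.483 (ITGB2 on 1 of 3 and ITGB1 on 1 of 6 probe sets), and CXCR4 fell by 0.22. ITGB2 and CXCR4 did not pass without the 4 pairs (log2 changes −0.403 and −0.174 in place of −0.792 and −0.22, adjusted p = 0.0537 and 0.0648). ITGAM and ITGB1 still passed there, with smaller log2 changes of −0.8 and −0.338 in place of −1.33 and −0.483. The adhesion list did not pass (adjusted p = 0.0653), although it did without the replicate block (adjusted p = 0.0293), after quantile normalization (adjusted p = 0.013) and in other settings.

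**Figure D3:**
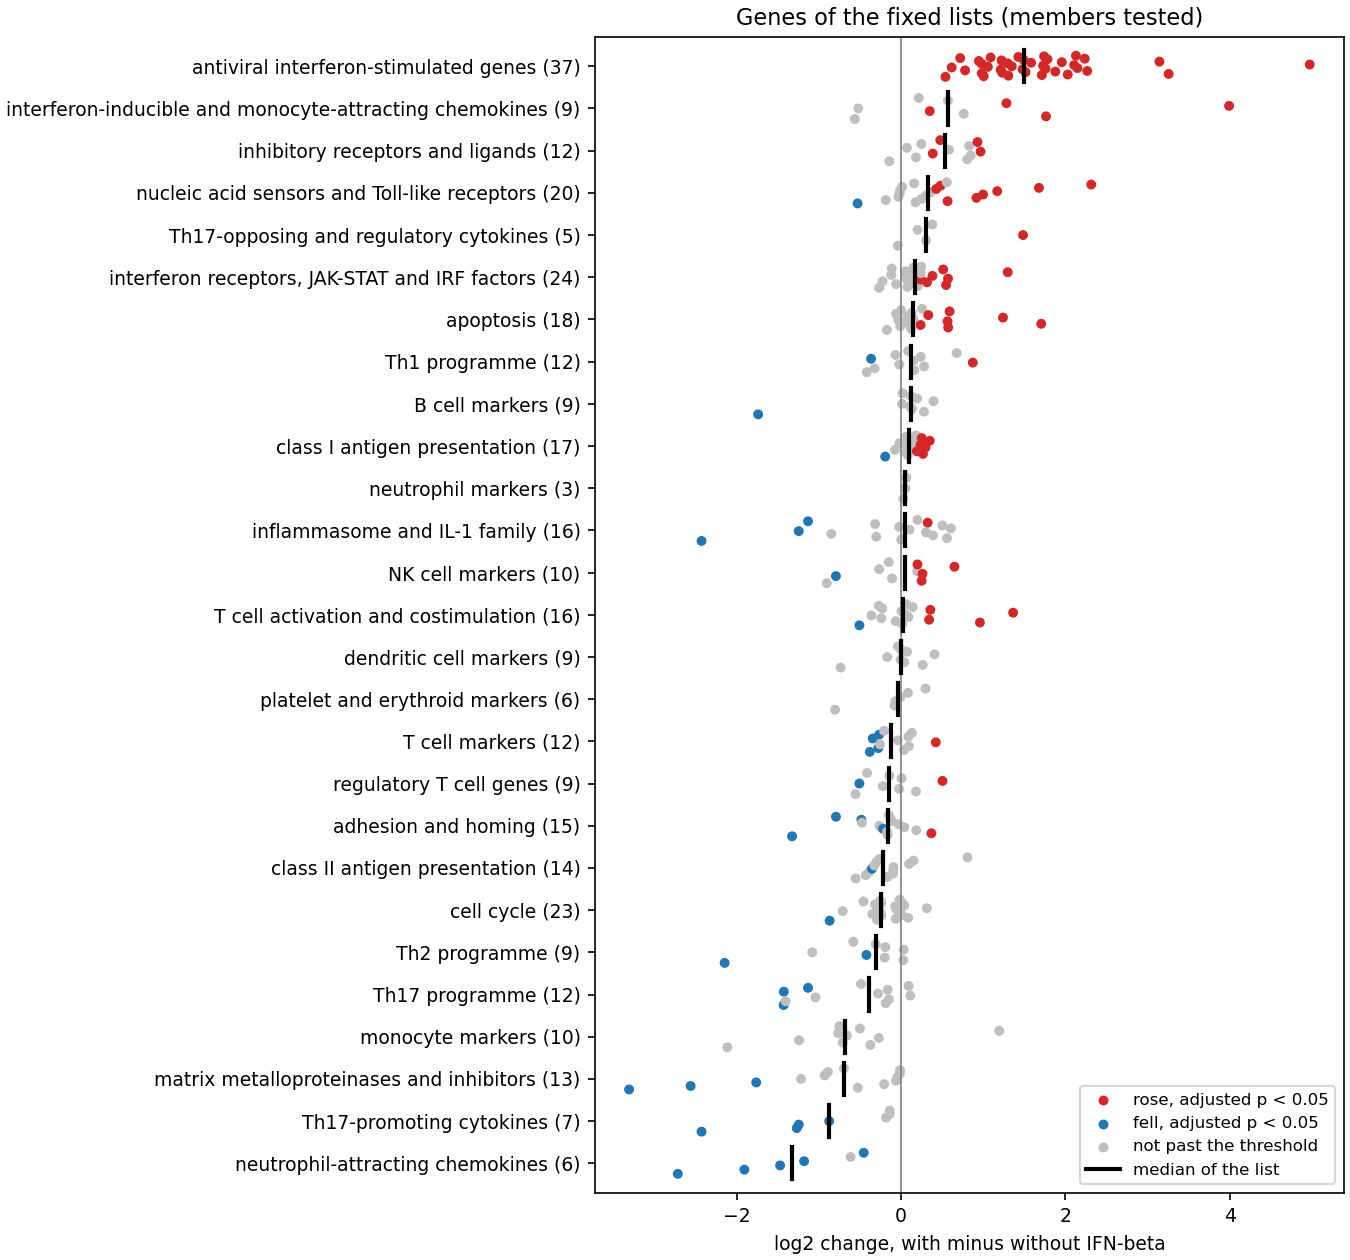
Log2 change (with minus without IFN-beta, horizontal axis) of each tested gene of the 27 lists fixed before the data were examined, ordered by list median, with the number of members tested after each name. Red and blue points are genes that rose or fell at an adjusted p of 0.05 over 15 donor pairs, grey points did not pass, and black bars are list medians, from 1.49 for the antiviral genes to −1.33 for the neutrophil-attracting chemokines.

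Markers of the cell types in PBMCs showed no list-wide change past the threshold in camera with the preset correlation. With fry the NK cell list passed, in the direction of higher values (adjusted p = 0.0311). Of 10 monocyte markers none passed, but their median was −0.684 (−0.208 without the 4 pairs above the ACTB ratio limit). Their log2 changes ran from −2.11 to 1.19, so not all were lower, and the values differed widely between pairs. CD14 had a log2 change of −0.766 (SE 0.348, adjusted p = 0.188), S100A9 of −0.75 (SE 0.328, adjusted p = 0.169) and S100A12 of −2.11 (SE 0.669, adjusted p = 0.054). The monocyte list had an adjusted p of 0.0573, and passed after quantile normalization (adjusted p = 0.0386), median centring (adjusted p = 0.0176) or an offset (adjusted p = 0.0422), with 7 of 15 pairs changing the call when left out. Of 12 T cell markers TRAT1 rose 1.34-fold and 4 fell, with log2 changes of −0.38 for CD4, −0.344 for CD3G, −0.277 for LCK and −0.267 for CD3D (list adjusted p = 0.392). CD4 and LCK did not pass without the 4 pairs (log2 changes −0.304 and −0.183, adjusted p = 0.061 and 0.0517). Of 10 NK cell markers the cytotoxic granule genes PRF1, GZMB, GNLY and NKG7, which activated T cells also express, rose by 0.65, 0.261, 0.251 and 0.199 on the log2 scale, FGFBP2 fell by 0.792, and 5 did not pass (4 rose and 3 fell when adjusted over the list alone; list adjusted p = 0.216). GZMB did not pass without the 4 pairs (log2 change 0.306 in place of 0.261, adjusted p = 0.0756). Of 9 B cell markers FCER2, the IgE receptor CD23, fell by 1.74, to 2.96 near the background, and 8 did not pass (list adjusted p = 0.314). None of 9 dendritic cell markers (list adjusted p = 0.816), 3 neutrophil markers (list adjusted p = 0.573) or 6 platelet and erythroid markers (list adjusted p = 0.736) passed over all genes, and in the platelet and erythroid list 1 rose and 2 fell when adjusted over the list alone. For lists with no such count given, the numbers adjusted over the list alone were the same as those over all genes.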

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

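Probe sets with no gene symbol or with several were kept out of the comparison by gene, yet part of them responded to IFN-beta. The paired limma fit was run on all 32768 probe sets above the level filter, and p-values were adjusted over all of them. There 364 of these 7483 passed an adjusted p of 0.05, with 165 higher and 199 lower. Of 6274 probe sets with no symbol 229 passed (116 higher, 113 lower), 22 of them by at least 2-fold. Of 1209 with several symbols 135 passed (49 higher, 86 lower), 2 of them by at least 2-fold. They came to attention as a signal in data that the report does not use, and no explanation was tested.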

How the results depend on the processing

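Leaving out the 4 pairs above the ACTB ratio limit was the one setting chosen after seeing the data. Dropping the replicate block had the strongest effect: 142 genes passed in place of 1544 (120 higher, 22 lower), and 63 in place of 139 by at least 2-fold. All 142 were among the 1544, the fit without pairing leaves the spread between donors in the error, and the adhesion list passed (adjusted p = 0.0293). In the other settings with all pairs between 1059 and 1862 genes passed. Without the 4 pairs 1055 passed, 899 of them shared, with 418 lower and 82 by at least 2-fold, and 24 of 89 calls among the named genes were lost. There the cell cycle list had an adjusted p of 0.0648, the adhesion list 0.0462, and the ACTB log2 ratio differed by 0.0554 (exact p = 0.043). In 50 random sets of 4 pairs left out, between 363 and 1621 genes passed (median 773.5), so fewer pairs lower the total by themselves. By at least 2-fold, 72 to 197 passed in these sets (median 118.5), so the 82 lies low within their range. Quantile normalization gave 44.1% and median centring 59.4% of calls higher, against 53%. With an estimated correlation 2 lists passed in place of 13. The adjusted p was then 0.0615 for the antiviral list, 0.109 for interferon signalling, 0.109 for class I, 0.109 for interferon-inducible chemokines, 0.181 for neutrophil-attracting chemokines, 0.203 for Th2, 0.181 for Th17, 0.109 for Th17-promoting cytokines, 0.0615 for apoptosis, 0.627 for the cell cycle and 0.195 for metalloproteinases. With fry, Th17-opposing cytokines (0.0372), adhesion (0.0278) and NK markers (0.0311) passed and the cell cycle (0.115) did not. The adhesion list passed with a random block (0.0419), quantile normalization (0.013), median centring (0.028) and the lowest 60% left out (0.0413). Monocyte markers passed with quantile normalization (0.0386), median centring (0.0176), the offset (0.0422) and the lowest 60% left out (0.0393), and class II with median centring (0.0456). The cell cycle list did not pass with no filter (0.0623), nor, with probe sets of possible cross-hybridization left out, did it (0.0666) or Th17-promoting cytokines (0.0552). In that last setting CFB turned to −0.117. The causes were not tested. With each of the 15 pairs left out in turn 1171 to 1675 genes passed, 13 to 15 lists passed, and adjusted p ran from 0.0253 to 0.399 for class II, 0.0173 to 0.139 for Th17-opposing cytokines, 0.00767 to 0.0577 for the cell cycle, 0.0307 to 0.101 for adhesion and 0.0153 to 0.224 for monocyte markers. The difference in the ACTB log2 ratio ran from −0.171 to 0.172, and passed 0.05 at 0.172, with 1 pair left out. The floor moved no count of calls, and the signed-rank test, run by gene, gave no list values. Signal over background limits genes near the low mode, of which CCNA1 is an example.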

Other observations

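Several gene families that were not fixed lists themselves had members past the threshold. TRIM22, of the TRIM family, is also a member of the antiviral list. The families and the genes named for them were chosen after their values were seen, so that counts are given and no test of a family. Of 13 PARP family genes, ADP-ribosyltransferases, 7 rose and none fell (median log2 change 0.522), with PARP12 2.17-fold and PARP9 1.77-fold higher. All 4 tested genes of the SP100 family of nuclear body proteins rose (median 0.667), SP100 and SP110 both by 1.70-fold. Both families kept these counts after quantile normalization, after median centring and without the 4 pairs above the ACTB ratio limit. Of 45 TRIM genes 9 rose and none fell, although 1 fell after quantile normalization, and 3 of 7 guanylate-binding proteins rose. With those 4 pairs left out 5 TRIM genes, 1 guanylate-binding protein and 3 of the immunoglobulin genes below rose. None of 7 metallothioneins passed.

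Of 17 immunoglobulin genes 6 rose and none fell, 4 rose after quantile normalization and 7 after median centring, and the constant regions IGHM and IGKC rose by 0.58 and 0.33 on the log2 scale, each in 15 of 15 pairs. Probe sets of immunoglobulin genes can pick up related segments. Among single genes, TNFSF13B, the B cell survival factor BAFF, rose 2.33-fold (10.45 ± 1.26 to 11.67 ± 0.69, SD, n = 15, adjusted p = 0.00456 in limma), and CXCL13, which attracts B cells, rose 2.74-fold. CD38 rose 3.63-fold, IL15 1.62-fold and its receptor chain IL15RA 2.29-fold. In the opposite direction 21 of 55 ribosomal protein genes fell and none rose, with a small median of −0.101, while 10 fell after quantile normalization, 18 after median centring and 16 without the 4 pairs. RPL3 fell by 0.296, in all 15 pairs. Of 86 genes of the respiratory chain and ATP synthase 15 fell and none rose (median −0.111), 22 fell after quantile normalization and 8 without the 4 pairs, and after median centring 12 fell and 1 rose.

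Other groupings of the arrays did not reach the count of called genes. Of 100 splits of the 30 arrays into 15 and 15, the real one included, 1 gave as many as 1544 calls, and the highest of the others gave 22. Among 100 assignments that part every donor pair, again with the real one, 1 gave as many, and the highest of the others gave 0. These others mix both conditions in each group, while the real one puts all arrays with IFN-beta on one side. The IFN-beta effect thus enters their error and keeps their counts low, and 100 splits allow no share below 1 in 100. The comparison therefore does not exclude chance. The tests of the explanations that follow were chosen after the results were seen.

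The antiviral response differed between pairs, and the cultures without IFN-beta differed most. Degraded RNA in the 4 pairs above the ACTB ratio limit does not account for it as the whole cause. Without them the SD of the response was 0.89, against 0.898 over all pairs, although those 4 pairs responded more (2.4 against 1.36, exact permutation test, p = 0.0491). Saturation of the arrays is also argued against, since the 15 antiviral genes that stayed below 13 on every array had a median SD ratio, without over with IFN-beta, of 2.1 (exact p = 0.00824 for their mean). A candidate explanation is that an interferon response was already under way in some cultures without added IFN-beta, but the larger spread there is the observation that prompted it and is no test of it. The highest mean of the 15 type I interferon genes over the cultures without added IFN-beta was 3.11, and 1 of these cultures had any of them above 4, at 4.26, which does not decide it either, since such transcripts may be gone by 24 h. Whether IFN-gamma made in the cultures set that level cannot be told apart from no relation: over the 15 cultures without IFN-beta, IFNG and the antiviral mean had a Pearson r of 0.487 (permutation p = 0.0656) and a Spearman rho of 0.389 (permutation p = 0.154, adjusted over both 0.154), and r was 0.443 without the 2 cultures farthest from the median IFNG level.

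The means of the neutrophil-attracting chemokines and Th17-promoting cytokines were lower with IFN-beta, over 13 genes by 1.12 ± 0.882 per pair (SD, n = 15), with 9 of the 13 called and 4 without the 4 pairs above the ACTB ratio limit, and neither list passed camera with an estimated correlation (adjusted p = 0.181 and 0.109). Degraded RNA in the 4 pairs as the whole cause is argued against, since without them the median change was −0.85 (−1.18 over all pairs) and the mean over the genes was still lower (exact sign-flip test over 11 pairs, p = 0.00195). The ACTB log2 ratio was still 0.0554 higher with IFN-beta in the 11 pairs (exact sign-flip test, p = 0.043), so RNA quality within them stays open. A smaller share of monocytes, or less monocyte RNA, may contribute and cannot be told apart from lower expression per cell. The 10 monocyte markers changed by −0.619 ± 1.54, with single markers from −2.11 to 1.19, so not all were lower. The 13 genes changed by −0.505 ± 1.46 more than the markers, in 10 of 15 pairs (exact sign-flip test, p = 0.199). In the 11 other pairs the median of the markers was −0.208, and the 13 genes changed by −0.692 ± 1.23 more than the markers (exact sign-flip test over 11 pairs, p = 0.0889), which leaves it open too.

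In the Th17 list 3 of 12 genes fell, 2 without the 4 pairs above the ACTB ratio limit, and the list did not pass camera with an estimated correlation (adjusted p = 0.181). A smaller share of all T cells as the whole cause would lower all T cell markers alike, if their expression per cell stayed the same. TRAT1 rose by 0.423, while CD4, CD3G, LCK and CD3D had log2 changes of −0.38, −0.344, −0.277 and −0.267. Expression per cell was not measured, so the markers argue against this cause only under that condition. The list changed by −0.541 ± 0.606 more than the mean of the 12 markers, lower in 12 of 15 pairs (SD, n = 15, exact sign-flip test, p = 0.00348). The genes that still fell without the 4 pairs, IL1R1 and KLRB1, are not made by Th17 cells alone. The difference from the markers therefore need not come from T cells. Degraded RNA in the 4 pairs is argued against as the whole cause. Without them the median of the list was −0.429, against −0.385 over all pairs, and its mean was still lower (exact sign-flip test over 11 pairs, p = 0.0205). In those 11 pairs the ACTB log2 ratio was still 0.0554 higher with IFN-beta (exact sign-flip test, p = 0.043). A part played by RNA quality within them therefore stays open. Lower expression of Th17 genes in T cells stays open as a hypothesis. So do fewer CD4 T cells and fewer NK cells that carry KLRB1, which were not tested. CD4 changed by −0.38 (−0.304 without the 4 pairs, no longer past the threshold), against a list median of −0.385 and a list mean of −0.625. In mixed cells the level of CD4 does not give the number of CD4 T cells.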
